A study of Homo sapiens with 4 samples.

How the data were processed

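RNA from serum-starved NCI-H295R cells given 25 mmol/L nicotinamide or distilled water for 24 h was enriched with oligo(dT) beads and sequenced on a BGISEQ-500 instrument, per the labels' protocols. Per the submitters' processing notes, the tools were Bowtie2 and RSEM, both listed with version 1.2.8, and the build was GRCh38. The annotation, the strand setting and any read filter are not given in the sources used here. The deposited table holds the authors' estimated read counts per gene (RSEM expected counts, with decimals) for 4 libraries, plus the authors' mean count of each group. RSEM divides reads that fit several transcripts among them, so genes with near-identical copies can lose or gain counts, and reads of overlapping or antisense genes cannot be told apart when strand is unknown. Samples were grouped by the treatment label, 2 vehicle and 2 NAM, and columns were tied to samples by the dose and replicate number in their names.

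The table has 29519 rows, of which 2998 are empty in every library. In 52 rows, 26 neighbouring pairs, the deposited group means belonged to the neighbouring row (tolerance 0.01 counts), so that the gene label of these rows is in doubt. They were left out, with 4 members of the gene lists among them. The remaining 26469 rows entered, 1921 of them at 0 in all libraries. Gene symbols were set by NCBI gene number through the RefSeq gene table for GRCh38, in which 24479 of 25247 numbers were found. This also restored 27 symbols that had been turned into dates. A further 4272 rows carry the submitters' own identifiers, 3260 of them with values. They held 15.3% to 19.2% of the counts, and a single such row held 13.8% of vehicle library 1 and 10.9% to 11.1% of the other libraries. Coordinates are those of the RefSeq table.

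Estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with its defaults (a minimum count of 10 and total of 15), TMM scaling (factors 0.854, 1.02, 1.07 and 1.07 for vehicle 1, vehicle 2, NAM 1 and NAM 2), glmQLFit and glmQLFTest on the group alone, and Benjamini-Hochberg adjustment over 17265 genes at 0.05. The SE of a log2 fold change is its size divided by the square root of its F statistic. The common dispersion was 0.039, a coefficient of variation of 19.7%. In 68.6% of genes the libraries of one group lay on the same side of both of the other, against 33.3% by chance. An exact permutation test of a single value with 2 libraries per group cannot go below that 33.3%. Log2 CPM correlated at r = 0.965 between the vehicle libraries, 0.987 between the NAM libraries and 0.916 to 0.941 between groups. The first principal component held 73.1% of the variance and the next 19.9%. Over genes with whole counts and a sum of at least 200, the variance between replicates was 21.7 times counting noise for vehicle and 1.92 times for NAM, so neither pair was treated as a single library deposited again; this does not show that they are separate cultures.

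Before the data were examined, 32 gene lists with 852 members were fixed, of which 828 were measured and 31 lists could be tested. Lists were tested with camera (limma 3.58.1, preset correlation of 0.01) and adjusted over the 31 lists. Genes in the text were named by a rule fixed at the same time: the 10 largest increases and decreases among genes that passed with at least 10 CPM in a group, no overlap between groups and an approved symbol; every measured androgen synthesis gene; up to 4 passing members per other list with the smallest adjusted p, or 2 where none passed; NAMPT, NNMT, SIRT1 and PARP1; and the 4 libraries' values of 6 steroid genes. Some genes that this rule names are not reported here, though they stay in the counts. Other list members named in the text, among them SRD5A1, HSD17B1, CITED2, MRAP, NR5A1, FADS3, CEBPB, XBP1, HYOU1, HSPA5, HSP90B1, ATF4, ATF3, MTHFD1, TYMS, AHCYL1, ECT2, AXIN2, COL4A1, IGF2, NMNAT2, NNT, PARP12, TNKS2, AKR1B10, TALDO1, XPC, AEN, SLC2A1, HK2, IRAK2 and BST2, were chosen after their values were seen. Alternatives were DESeq2 size factors, total-count and upper-quartile scaling, no filter or a stricter one, a replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, glmTreat against 1.5-fold, and for lists an estimated correlation and fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. After the data were seen, 3 were added: a correction for transcript length (each library's smooth trend against log2 length, lowess span 0.3), the 52 doubtful rows kept, and only rows with NCBI numbers. Length was that of the longest GENCODE 29 transcript, known for 85.6% of the genes tested. Shared sequence was the percentage of a gene's 50-base windows in those transcripts that also occur in another gene, and the larger it is the less certain the value. It was computed for part of the genes named; of these, the largest shares not given in the text are those of NAMPT (17.2%), PHLDA3 (16.1%), SLC25A51 (15.6%) and QPRT (15.6%).

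The method was tested on simulated data with the real means and depths of this comparison. Each gene had a single estimated dispersion, shared by both groups. In the data the vehicle pair varied more than the NAM pair (21.7 against 1.92 times counting noise). Far fewer genes were changed in the simulation than the 3279 called here, which makes the adjusted threshold stricter. The shares called are therefore those of the simulation and not of this comparison. Of 16847 simulated genes tested with no length trend, 1 of 52 changed 1.5-fold, 14 of 75 changed 2-fold and 46 of 66 changed 4-fold were called, along with 6 of 16654 unchanged genes. With a length trend simulated in vehicle library 1, 0 of 52, 8 of 75 and 41 of 68 were called, along with 4 of 16630 unchanged genes. Of 200 lists of unchanged genes, 5 had a camera p under 0.05. The simulated genes varied independently, so this gives no error rate for lists whose members vary together. The androgen synthesis list, for example, had an estimated correlation of 0.572.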

Results

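Messenger RNA was measured in 4 libraries of NCI-H295R cells, a human adrenocortical carcinoma line that makes adrenal steroid hormones and is widely used to study their synthesis. The cells were serum starved and received either 25 mmol/L nicotinamide (NAM), the amide form of vitamin B3 and a precursor of NAD, or distilled water as vehicle for 24 h. There were 2 libraries per group. Estimated read counts totalled 18779525 and 18293834 in vehicle libraries 1 and 2 and 18195788 and 18336405 in NAM libraries 1 and 2. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Gene levels are given as CPM, the standard read count scaled to library size, and as log2 fold changes of NAM minus vehicle with their standard error (SE).

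The first comparison asked which transcripts differed after nicotinamide. Of 17265 genes tested with edgeR's quasi-likelihood test, 1406 were significantly higher and 1873 significantly lower in NAM-treated cells at a Benjamini-Hochberg adjusted p under 0.05, and 715 of the higher and 1143 of the lower genes differed at least 2-fold. The largest increases among genes with at least 10 CPM in a group were in NGFR, a neurotrophin receptor (log2 fold change 5.60, SE 0.42, from counts of only 13 and 5 in vehicle, and 6.56 without vehicle library 1 or 4.97 without vehicle library 2), GOLGA4, a Golgi tethering protein (4.95, SE 0.21, from counts of only 15 and 22 in vehicle), INHBE, an inhibin subunit (4.12, SE 0.21), and TRIB3, a stress-induced pseudokinase (4.07, SE 0.25). CHAC1, which degrades glutathione, ULBP1, a ligand of a natural killer cell receptor, SMPD3, a neutral sphingomyelinase, EFNB2, an ephrin, TLN2, a talin, and ASNS, asparagine synthetase, completed the 10 largest increases, with log2 fold changes from 3.33 for ASNS to 3.99 for CHAC1. The largest decreases reported here were in GSTA2, an alpha-class glutathione S-transferase (-5.48, SE 0.50), IGF1, the insulin-like growth factor (-4.75, SE 0.18), and PIAS1, a SUMO ligase (-4.74, SE 0.57). They were followed by KRT80 (-4.25), SULT2A1 (-4.22), DAPP1 (-4.15), PI15 (-4.08), ECM2 (-3.98) and FABP3 (-3.98). Leaving out 1 library also moved the fold of SMPD3 (4.44 without vehicle library 1), GSTA2 (-6.33 without NAM library 1) and PIAS1 (-4.06 without vehicle library 1) by over 1.5 times. ASNS and GSTA2 are uncertain, since 40.6% and 18.4% of their 50-base transcript windows occur in another gene. IGF1 fell from 46.2 ± 4.0 CPM in vehicle to 1.72 ± 0.03 CPM in NAM libraries (SD, n = 2 each; adjusted p = 0.00701). The count of changed genes depended on which libraries set the spread: it was 354 without NAM library 1, 336 without NAM library 2, 8204 without vehicle library 1 and 10579 without vehicle library 2. With scaling by total counts alone, which moved the median log2 fold change of all genes from 0.01 to 0.19, 56.3% of the changed genes were higher in NAM, against 42.9% with the main scaling.

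By its title, the series addressed how the vitamin acts on androgen production, so the enzymes of that pathway were compared next. Of its 12 measured genes, 5 fell, 7 did not pass and none rose; adjusted over the list alone, 8 were lower. SULT2A1, the sulfotransferase that makes dehydroepiandrosterone sulfate, fell 18.7-fold, from 72.8 ± 15.6 to 3.89 ± 0.50 CPM (log2 fold change -4.22, SE 0.23, adjusted p = 0.00701). CYP11A1, which cleaves the side chain of cholesterol to give pregnenolone, fell 4.87-fold from 139.6 ± 47.3 to 28.7 ± 2.4 CPM (-2.28, SE 0.27, adjusted p = 0.0140). CYP17A1, the hydroxylase and lyase that directs steroids to androgens, fell 4.39-fold from 85.1 ± 9.4 to 19.4 ± 1.1 CPM (-2.13, SE 0.15, adjusted p = 0.00794). HSD3B2, which converts pregnenolone to progesterone, fell 4.83-fold from 15.6 ± 7.2 to 3.23 ± 0.08 CPM (-2.27, SE 0.38, adjusted p = 0.0239). AKR1C3, which reduces androstenedione to testosterone, fell 2.41-fold from 114.7 ± 41.8 to 47.5 ± 3.3 CPM (-1.27, SE 0.27, adjusted p = 0.0388). STAR, which carries cholesterol into mitochondria, stood at 246.6 ± 52.1 CPM in vehicle and 237.1 ± 25.0 CPM in NAM libraries and did not pass (-0.06, SE 0.20, adjusted p = 0.853), its sign turning with total-count or upper-quartile scaling. The others that did not pass were PAPSS2 (-1.34), the ferredoxin reductase FDXR (-1.12), ferredoxin FDX1 (-0.54), CYB5A (-0.34), HSD17B3 (-0.03, above 0 with total-count or upper-quartile scaling) and the electron donor POR (0.33). The HSD17B3 value is uncertain, since 55.4% of its 50-base windows occur in another gene.

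In the separate libraries, vehicle 1, vehicle 2, NAM 1 and NAM 2 in that order, STAR was at 283.4, 209.8, 254.8 and 219.4 CPM, CYP11A1 at 173, 106.1, 30.3 and 27.0 CPM, CYP17A1 at 91.7, 78.4, 20.1 and 18.6 CPM, and HSD3B2 at 20.7, 10.5, 3.28 and 3.17 CPM. CYP11B1, the last enzyme of cortisol synthesis, was near the detection limit at 0.811, 0.963, 0.667 and 0.562 CPM (-0.53, SE 0.45, adjusted p = 0.431). CYP21A2 had estimated counts of 4.78, 4.86, 0 and 0, too few to be tested, and 33.2% of the 50-base windows of its transcripts also occur in another gene. On GRCh38, SULT2A1 (NCBI gene 6822) lies on chromosome 19 at 47870467 to 47886315, CYP11A1 (1583) on chromosome 15 at 74337762 to 74367646, CYP17A1 (1586) on chromosome 10 at 102830531 to 102837413, HSD3B2 (3284) on chromosome 1 at 119414931 to 119423034, AKR1C3 (8644) on chromosome 10 at 5048781 to 5107686, and STAR (6770) on chromosome 8 at 38142700 to 38150952. As a group the androgen synthesis genes were lower relative to other genes in the camera test with a preset correlation (adjusted p = 4.67e-06, median log2 fold change -1.20, and -0.69 without vehicle library 1). The call was lost with an estimated correlation (adjusted p = 0.605). This was so for each of the 14 lists that passed with the preset one. With 4 libraries in 2 groups, that version of camera has 2 residual degrees of freedom, so few lists could pass it. Its losses therefore neither show nor exclude that correlation within a list made the call. The estimated correlation was 0.913 for ribosomal proteins, 0.72 for the respiratory chain and 0.572 for androgen synthesis. It was 0.49 for cholesterol biosynthesis, 0.445 for mitosis and 0.295 for replication. Camera p-values with the preset 0.01 may be too small for such lists. The estimate was negative for the Wnt, matrix, fatty acid, and endothelial and fibroblast lists, and 0.0575 to 0.212 for the others that passed. HSD3B2 did not pass without either NAM library (adjusted p up to 0.0663), nor did AKR1C3 (up to 0.180), which also did not pass without a filter (adjusted p = 0.0568), while SULT2A1, CYP11A1 and CYP17A1 passed in all 15 alternatives. Without vehicle library 1 the log2 fold change was -0.84 for AKR1C3, -0.54 for FDXR and -0.33 for FDX1.

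**Figure D1:**
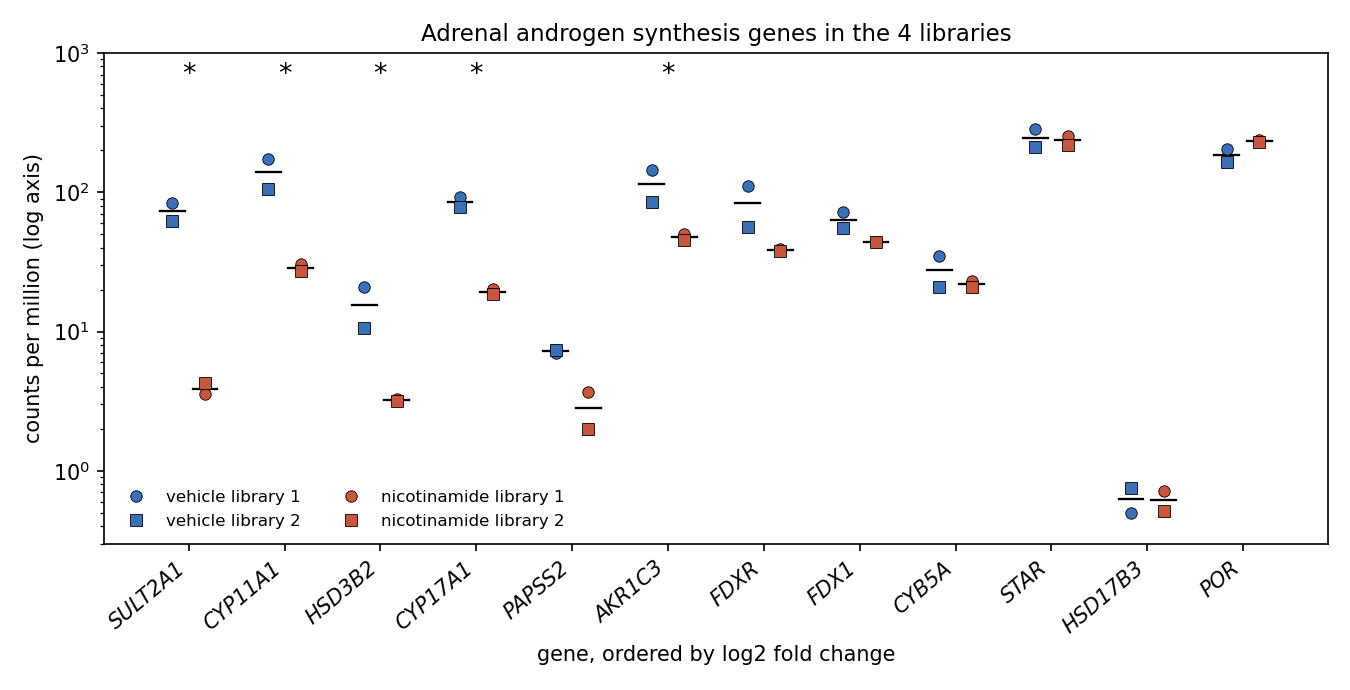
Normalised read counts in CPM (vertical axis, log scale) of the 12 androgen synthesis genes in each library, ordered by log2 fold change; circles are library 1 and squares library 2 of vehicle (blue) and nicotinamide (red), bars are group means of 2 libraries, and asterisks mark an adjusted p under 0.05. SULT2A1 falls from 72.8 to 3.89 CPM on average, while STAR lies between 209.8 and 283.4 in all 4 libraries.

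The wider list of steroid hormone synthesis had 21 tested genes, of which 5 fell, 2 rose and 14 did not pass. Adjusted over the list alone, 8 were lower and 2 higher. The list holds all 12 androgen synthesis genes, and the 5 that fell are those named above, so it is not separate evidence. The 2 that rose were SRD5A1 (0.68), a steroid reductase, and HSD17B1 (0.78), an estrogen-forming dehydrogenase. The list was lower in camera (adjusted p = 0.00423; adjusted p = 0.605 with an estimated correlation), and not with a filter of at least 10 CPM (adjusted p = 0.160). Among 28 regulators of steroidogenesis and genes of ACTH or angiotensin signalling, 5 fell and 1 rose, the same counts as adjusted over the list alone. PDE11A, a cyclic nucleotide phosphodiesterase (-1.97, SE 0.18), the orphan receptor NR2F1 (-1.06), the adenylate cyclase ADCY3 (-0.69), the transcriptional coregulator CITED2 (-0.77) and MRAP, which brings the ACTH receptor to the cell surface (-2.81, SE 0.64), were lower, and NR4A2, an orphan receptor, was higher (1.63, SE 0.27). The main steroidogenic transcription factor gene NR5A1 did not pass (-0.22, adjusted p = 0.404), and this list did not move relative to other genes (camera adjusted p = 0.514).

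Of 21 cholesterol biosynthesis genes tested, 11 fell, 10 did not pass and none rose (16 lower adjusted over the list alone). ACAT2 (-2.21, SE 0.26), HMGCS1, which makes the precursor of mevalonate (-1.68, SE 0.13), HSD17B7 (-1.37, SE 0.16) and MSMO1 (-0.97, SE 0.12) had the smallest adjusted p-values (0.00914 for HMGCS1). The camera adjusted p was 4.63e-07, and the adjusted p = 0.605 with an estimated correlation. In fatty acid synthesis and desaturation, 6 of 19 genes fell and 1 rose (10 lower and 2 higher adjusted over the list alone), including the desaturases FADS2 (-1.75, SE 0.14) and FADS1 (-1.17, SE 0.13), fatty acid synthase FASN (-1.25, SE 0.13) and the acyl-CoA synthetase ACSL4 (-0.89, SE 0.12); FADS3 rose (1.03). That list passed camera (adjusted p = 0.0220; adjusted p = 0.605 with an estimated correlation) but not without NAM library 1 or NAM library 2 or with total-count scaling (adjusted p up to 0.118). Of 18 genes of cholesterol uptake, storage and efflux, 3 fell and 1 rose (5 lower and 3 higher adjusted over the list alone), and the list did not pass (adjusted p = 0.647). SREBF1, a transcription factor of lipid synthesis (-0.83, SE 0.11), and VLDLR, a lipoprotein receptor (-0.74, SE 0.16), were among the lower genes. NPC1, which exports cholesterol from lysosomes, was higher (1.14, SE 0.16).

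The unfolded protein and integrated stress response list had the smallest adjusted p of all lists in the main camera test, though not in fry. Of its 26 tested genes 13 rose, 1 fell and 12 did not pass (15 higher and 1 lower adjusted over the list alone). TRIB3 rose from 16.9 ± 5.1 to 283 ± 1.3 CPM, CHAC1 from 5.60 ± 1.26 to 88.6 ± 5.4 CPM and ASNS from 18.5 ± 5.7 to 185.7 ± 0.9 CPM (SD, n = 2 each; adjusted p = 0.00701, 0.00701 and 0.00843). DDIT4, an inhibitor of mTOR signalling, rose as well (2.36, SE 0.13), as did the cystine transporter SLC7A11 (2.14), CEBPB (1.75), XBP1 (1.66), HYOU1 (1.66) and the endoplasmic reticulum chaperone HSPA5 (0.78). The chaperone HSP90B1 (0.08) and the transcription factors ATF4 (0.57) and ATF3 (0.72) did not pass, and VLDLR was the gene that fell. The list was higher in camera (adjusted p = 2.40e-15; adjusted p = 0.506 with an estimated correlation). Of 22 genes of the methionine cycle, folate and serine, 6 rose and 3 fell (8 higher and 5 lower adjusted over the list alone). PSAT1, a serine synthesis enzyme, rose from 100.5 ± 4.9 to 783.5 ± 3.1 CPM (2.96, SE 0.14, adjusted p = 0.00701), CBS, which makes cystathionine, rose (2.54, SE 0.14), and so did MTHFD2, a mitochondrial folate enzyme (1.68, SE 0.15). MTHFD1 (-0.83) and thymidylate synthase TYMS (-0.79) were among those that fell. CBS is uncertain because 54.5% of its 50-base windows occur in another gene, and AHCYL1, counted among the genes that rose, had counts of 0 and 0 in vehicle and 30 and 13 in NAM libraries. This list passed camera upward (adjusted p = 0.0219; adjusted p = 0.647 with an estimated correlation), and did not pass without NAM library 1, without a filter or with a filter of at least 10 CPM (adjusted p up to 0.164).

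Replication and mitosis genes were compared next. In DNA replication and S phase, 18 of 32 genes fell, 14 did not pass and none rose (23 lower adjusted over the list alone), led by RRM2, a subunit of ribonucleotide reductase (-1.92, SE 0.12, adjusted p = 0.00701; 20.2% of its 50-base windows occur in another gene), GINS3 (-1.41, SE 0.16) and CDC45 (-1.18, SE 0.14), parts of the replicative helicase, and its core subunit MCM7 (-1.52, SE 0.20). In mitosis and G2/M, 19 of 33 genes fell, 1 rose and 13 did not pass (27 lower and 1 higher adjusted over the list alone). The spindle checkpoint genes BUB1B (-1.13, SE 0.11) and MAD2L1 (-1.50, SE 0.20), the spindle protein NUSAP1 (-1.04, SE 0.14), 54.3% of whose 50-base windows occur in another gene, and the cytokinesis protein ANLN (-0.91, SE 0.13) were lower, and ECT2 was higher (0.55). Camera gave adjusted p = 3.03e-09 for replication and 1.76e-07 for mitosis, and with an estimated correlation adjusted p = 0.605 and 0.624. Of 21 Wnt and beta-catenin target genes, 14 fell, 7 did not pass and none rose (17 lower adjusted over the list alone). APCDD1, a Wnt inhibitor, fell from 1024 ± 110.5 CPM by 1.91 on the log2 scale, the stem cell receptor LGR5 fell by 1.54, ISM1 fell by 2.26, MYC fell by 1.17 and the negative regulator AXIN2 fell by 2.04 (camera adjusted p = 1.19e-10; adjusted p = 0.506 with an estimated correlation).

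In extracellular matrix and epithelial-mesenchymal genes, 11 of 33 fell, 22 did not pass and none rose (13 lower adjusted over the list alone). Smooth muscle actin ACTA2 (-3.80, SE 0.28), the matrix protein TGFBI (-2.80, SE 0.24) and the matrix protease MMP2 (-1.04, SE 0.13) were lower, and COL4A1, counted among those that fell, had counts of 26 and 10 in vehicle and 0 and 0 in NAM libraries. The list was lower in camera (adjusted p = 3.37e-05; adjusted p = 0.506 with an estimated correlation). Of 10 endothelial and fibroblast markers tested, 4 fell (7 adjusted over the list alone): ACTA2, COL3A1, a collagen expressed by this line at 1152 ± 11 CPM in vehicle libraries (-1.10, SE 0.14), FAP (-1.18, SE 0.16) and THY1 (-1.36, SE 0.24). That list had a camera adjusted p = 0.00114 and an adjusted p = 0.506 with an estimated correlation, and 3 of its genes also belong to the matrix list. In the IGF2 locus and IGF axis, 2 of 15 genes fell and 1 rose (6 lower and 1 higher adjusted over the list alone). IGF1 and the binding protein gene IGFBP5 (-1.96, SE 0.17) fell, IGFBP3 rose from 6.98 to 27.9 CPM on average, and IGF2 itself, with 23.4% of its 50-base windows shared with another gene, did not pass (-0.14). The list passed camera downward (adjusted p = 0.0267; adjusted p = 0.605 with an estimated correlation) but not in 5 alternatives, among them without vehicle library 2 and without NAM library 1 (adjusted p up to 0.613).

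**Figure D2:**
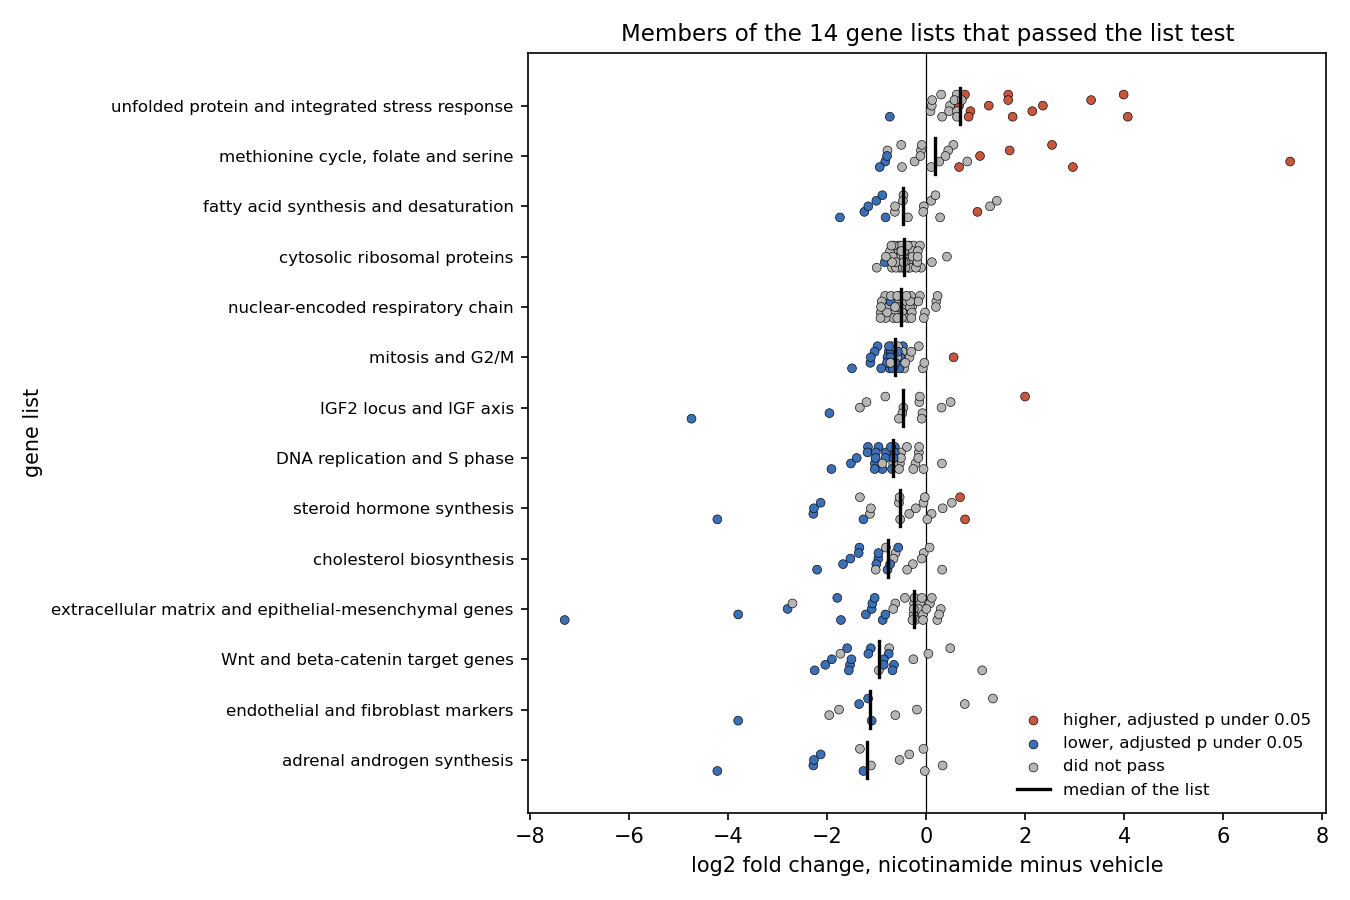
Log2 fold change, nicotinamide minus vehicle (horizontal axis), of each tested member of the 14 gene lists that passed the camera test with a preset correlation; red and blue points have an adjusted p under 0.05, grey points did not pass, and black bars are list medians. The stress response list lies to the right with a median of 0.69 and the androgen synthesis list to the left with a median of -1.20 (-0.69 without vehicle library 1); the far points, AHCYL1 at the right and COL4A1 at the left, are against a group with no counts and are no measure of size.

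Genes that use or bind nicotinamide and NAD went both ways. Among 19 genes of NAD and nicotinamide metabolism, 3 rose and 3 fell (the same counts adjusted over the list alone; camera adjusted p = 0.644). SLC25A51, the mitochondrial NAD carrier (1.28, SE 0.17), the NAD kinase NADK2 (0.98, SE 0.13) and NMNAT2, an enzyme of NAD synthesis with only 0.370 CPM in vehicle (2.02, SE 0.45), were higher. QPRT, an enzyme of NAD synthesis from tryptophan (-1.18, SE 0.20), the aldehyde oxidase AOX1 (-1.88, SE 0.41) and the transhydrogenase NNT (-0.53) were lower. AOX1 stood at only 2.66 CPM in vehicle and 0.717 CPM in NAM libraries and passed in 10 of 14 alternatives. NAMPT, the salvage enzyme that uses nicotinamide, was at 137.1 ± 8.8 CPM in vehicle and did not pass (0.34, SE 0.13, adjusted p = 0.119), nor did NNMT, which methylates nicotinamide and was at 1.17 ± 0.16 CPM (-0.66, SE 0.50, adjusted p = 0.383). Of 19 sirtuin and PARP genes, whose enzymes consume NAD and are inhibited by nicotinamide, 5 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.550). SIRT7 (0.95, SE 0.18), PARP6 (0.84, SE 0.17), PARP12 (0.59), TNKS2 (0.53) and SIRT1 (0.62, SE 0.15, adjusted p = 0.0492) rose, and PARP8 (-0.75, SE 0.12), PARP3 (-0.83, SE 0.19) and PARP1 (-0.59, SE 0.13, adjusted p = 0.0424) fell. Of 15 alternatives, SIRT1 passed in 9, PARP1 in 10, PARP3 in 11, PARP6 and PARP8 in 12 and SIRT7 in 13. With total-count scaling SIRT1, PARP1, PARP3, PARP6 and PARP8 did not pass.

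The oxidative stress, p53, apoptosis, glycolysis and autophagy lists did not pass camera, though single genes moved. Of 28 NRF2 and oxidative stress genes 4 rose and 2 fell (4 higher and 3 lower adjusted over the list alone). Both subunits of the glutathione synthesis enzyme, GCLC (0.96, SE 0.12) and GCLM (0.84, SE 0.13), the cystine transporter SLC7A11 and sulfiredoxin SRXN1 (1.77, SE 0.14) were higher. Of the windows of SRXN1, 84.8% occur in another gene. The reductase AKR1B10, with a mean of 1.99 CPM in vehicle, and transaldolase TALDO1 (-0.90) were lower. Of 24 p53 target genes 3 rose and 3 fell (4 higher and 4 lower adjusted over the list alone). GDF15, a stress cytokine, had counts of 5 and 4 in vehicle and 111 and 135 in NAM libraries (4.56, SE 0.39). The death receptor TNFRSF10B (1.28, SE 0.16) and the DNA repair gene XPC (0.66) also rose, and PHLDA3 (-1.73, SE 0.19), FBXW7 (-1.31, SE 0.13) and AEN (-1.01) fell. Of 26 apoptosis regulators 3 rose and 1 fell (3 higher and 3 lower adjusted over the list alone). HRK (2.42, SE 0.19), TNFRSF10B and PMAIP1 (1.27, SE 0.19), which promote cell death, rose, and the anti-apoptotic BCL2L1 fell (-0.89, SE 0.16). Of 27 glycolysis and hypoxia genes 3 rose and 3 fell (4 higher and 8 lower adjusted over the list alone). The angiogenic factor VEGFA (1.74, SE 0.13), the glucose transporter SLC2A1 (0.66) and hexokinase HK2 (0.97) rose, and NDRG1 (-1.56, SE 0.18), PDK1 (-1.37, SE 0.16) and LDHA (-1.36, SE 0.23) fell. Of 29 autophagy and lysosome genes 2 rose and 2 fell, the same counts as adjusted over the list alone. WIPI1 (0.80, SE 0.13) and the protease CTSB (0.86, SE 0.18) rose, and NAGLU (-0.85, SE 0.14) was among those that fell. The camera adjusted p-values of these 5 lists, in this order, were 0.514, 0.891, 0.647, 0.468 and 0.868. In the oxidative stress and autophagy lists the median and mean were below 0 while the test pointed up, and for the apoptosis regulators the median alone was below 0. The oxidative stress list passed upward without vehicle library 1 (adjusted p = 0.000618), and the glycolysis list passed downward without vehicle library 2 (adjusted p = 0.000128).

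Inflammatory and immediate early genes did not pass as lists either. Of 18 NF-kB and cytokine genes 6 fell and 2 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.468). The chemokines CCL2 (-2.91, SE 0.30), CXCL2 (-1.66, SE 0.34) and CXCL10, whose vehicle counts were only 23 and 14 (-3.71, SE 0.74), fell. NFKB2, a subunit of the transcription factor (2.69, SE 0.16), and the signalling kinase gene IRAK2 (1.03) rose. Of 32 interferon response genes 4 fell and 1 rose, likewise adjusted over the list alone (camera adjusted p = 0.0976). IFI44L (-1.38, SE 0.18), IFIT1 (-1.05, SE 0.17), OAS3 (-0.90, SE 0.13) and BST2 (-1.29) fell, and IRF1 rose (0.88, SE 0.14). Of 21 immediate early genes 2 fell and 2 rose, likewise adjusted over the list alone (camera adjusted p = 0.550). EGR1 (-3.07, SE 0.22) and MYC fell, and NR4A2 and KLF4 (1.31, SE 0.29) rose. The immediate early list passed downward without vehicle library 2 (adjusted p = 1.50e-10) and pointed up without vehicle library 1 (adjusted p = 0.141).

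Markers of cell types other than the cortex were tested on few genes. Of 12 adrenal medulla and neural markers 2 fell and 1 rose (3 lower and 2 higher adjusted over the list alone): the granins CHGB (-1.84, SE 0.12, from 133.7 ± 7.2 CPM) and SCG2 (-2.48, SE 0.47) fell and SYP rose (0.93, SE 0.14); the list's median and mean were above 0 while the test pointed down (adjusted p = 0.989). None of 3 leukocyte markers passed (camera adjusted p = 0.834), CD8A (0.54, adjusted p = 0.169) and ITGAX (-0.35, adjusted p = 0.423) having the smallest p-values. Of 6 hepatocyte and kidney epithelial markers, the apolipoprotein gene APOA2 rose from 18.4 ± 1.8 CPM (1.87, SE 0.14, adjusted p = 0.00843; camera adjusted p = 0.0762), and 2 were higher adjusted over the list alone. None of 6 cancer-testis and germline genes passed in edgeR, MAGEB2 (-0.82, adjusted p = 0.0644) and MAGEC1 (-0.33, adjusted p = 0.105) having the smallest p-values (camera adjusted p = 0.516). Of 15 replication-dependent histone genes 2 rose, also adjusted over the list alone: H2BC5 (0.98, SE 0.21) and H2BC4, with estimated counts of 0 and 1.95 in vehicle and 40.5 and 91.9 in NAM libraries (camera adjusted p = 0.514). Genes of the mitochondrial genome were not analysed here.

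Vehicle libraries 1 and 2 differed from each other more than NAM libraries 1 and 2 did. The median absolute log2 difference was 0.356 between the vehicle libraries and 0.101 between the NAM libraries, and 11.3% and 2.67% of genes differed over 2-fold within a pair. Across genes, vehicle library 1 was higher than vehicle library 2 for short transcripts, with a median log2 difference of 0.36 in the shortest of 5 length classes and -0.25 in the longest. The calls of 2 lists were lost without vehicle library 1. In the nuclear-encoded respiratory chain only SDHA of 40 genes passed (-0.72, SE 0.12), none adjusted over the list alone, with a list median of -0.52 (camera adjusted p = 0.00591; adjusted p = 0.873 with an estimated correlation). In the cytosolic ribosomal proteins only RPL7A of 48 genes passed (-0.84, SE 0.16; 25.8% of its 50-base windows shared with another gene), none adjusted over the list alone, with a list median of -0.45 (camera adjusted p = 0.0449; adjusted p = 0.873 with an estimated correlation). Without vehicle library 1 the median was -0.14 for the respiratory chain (adjusted p = 0.206) and 0.07 for the ribosomal proteins (adjusted p = 0.194, direction turned). Without vehicle library 2 the medians were -0.78 and -0.86, and the ribosomal protein call was also lost with only the genes that have NCBI numbers (adjusted p = 0.0566) and with length correction (adjusted p = 0.196).

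**Figure D3:**
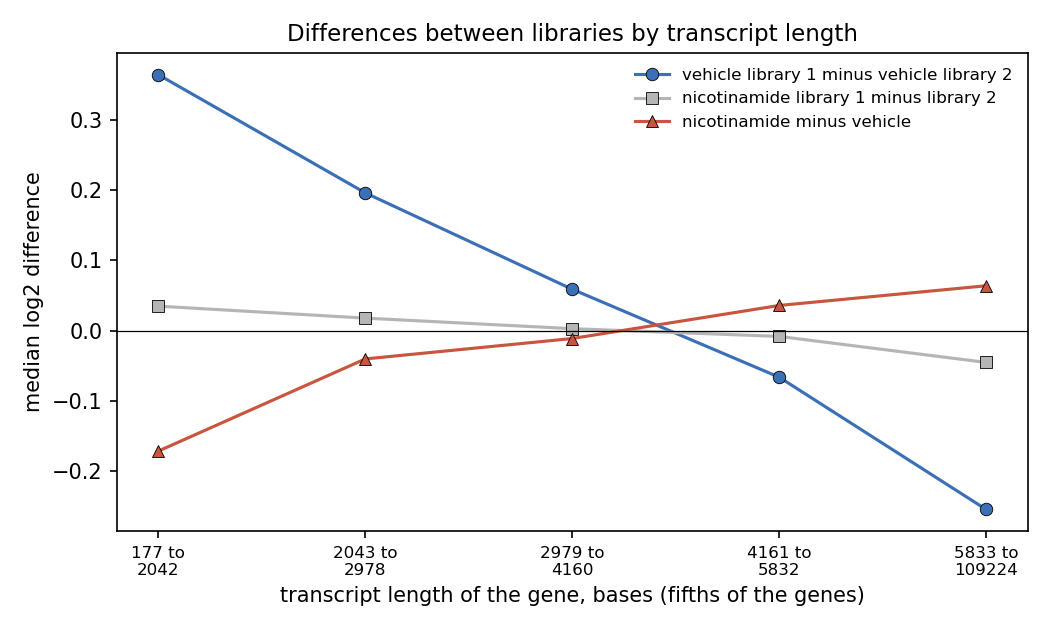
Median log2 difference between libraries (vertical axis) in 5 equal classes of the genes by length of the longest annotated transcript in bases (horizontal axis), for vehicle library 1 minus vehicle library 2 (blue circles), NAM library 1 minus NAM library 2 (grey squares) and NAM minus vehicle (red triangles). The vehicle pair runs from 0.36 in the shortest class to -0.25 in the longest, the NAM pair from 0.04 to -0.05 and the treatment difference from -0.17 to 0.06.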

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

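With 2 libraries per group the spread rests on very few values, and where a group was left with 1 library that library was assumed to vary like the other group. The length correction, the doubtful rows and the restriction to NCBI gene numbers were chosen after seeing the data. Leaving out each library gave 336 to 10579 changed genes (132 to 5140 higher, 204 to 5439 lower) and 336 to 4268 changed at least 2-fold (132 to 2253 higher, 204 to 2015 lower). The low ends came without NAM library 2 (354 without NAM library 1), when the spread came from the vehicle pair, and the high ends without vehicle library 2 (8204 changed without vehicle library 1), when it came from the closer NAM pair. Of the 3279 genes reported as changed, 334 and 323 were called without NAM library 1 and 2, and 3258 and 3270 without vehicle library 1 and 2, all in the same direction. Total-count scaling gave 1049 lower genes, 704 of them at least 2-fold. A filter of at least 10 CPM, which tests fewer genes, gave 1035 genes changed at least 2-fold (399 higher, 636 lower), and glmTreat, which tests a stricter question, 790 (293 higher, 497 lower). In all other alternatives these counts stayed within 1.5 times. DESeq2 called 3848 genes, 3043 of them shared, and limma-voom 3331, 3193 of them shared.

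Whether replicate numbers mark a pairing was not clear. The differences between libraries 1 and 2 of the groups correlated across genes at r = -0.01 (Spearman 0.14). Library 1 minus library 2 followed transcript length in the same direction in both groups (Spearman rho -0.355 for vehicle and -0.154 for NAM). With only 2 pairs these values neither show nor exclude a pairing. The replicate block gave 3931 changed genes, 3007 of them shared with the reported ones.

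With an estimated correlation 0 of 31 lists passed camera (2 at an unadjusted p under 0.05), and fry called 6. For androgen synthesis the adjusted p was 0.605 and 0.111 in these, and at most 0.00117 in the other 13 alternatives. The Wnt list also lost its call, though its estimated correlation of -0.0413 lay below the preset 0.01. Its unadjusted camera p was 7.66e-12 with the preset and 0.0173 with the estimate. Fry called the fatty acid, stress response, Wnt, matrix, endothelial and fibroblast, and hepatocyte and kidney lists. The last had not passed camera (fry adjusted p = 0.0394). The other lists called by camera did not pass fry. Besides androgen synthesis, its adjusted p was 0.0713 for replication, mitosis and methionine, 0.0916 for the IGF axis and 0.0956 for cholesterol biosynthesis. It was 0.109 for steroid hormone synthesis, 0.375 for the respiratory chain and 0.567 for ribosomal proteins. Lists that had not passed changed direction as follows (adjusted p), and the cause was not tested: adrenal medulla markers with total counts (0.939), the block (0.992), length correction (0.801), NCBI numbers only (0.969) and without either NAM library (0.811 to 0.951 over the 4 libraries left out); p53 targets with the stricter filter (0.888), the block (0.992) and without either vehicle library (0.811 to 0.976). Without vehicle library 1 immediate early genes turned (0.141; 1.50e-10 to 0.516 over the 4), without vehicle library 2 oxidative stress (0.463; 0.000618 to 0.854), histones (0.849; 0.323 to 0.849) and autophagy (0.849; 0.391 to 0.951), and without NAM library 1 autophagy and leukocyte markers (0.951; leukocytes 0.811 to 0.955). Ribosomal proteins, which had passed, turned without vehicle library 1 (0.194; 7.95e-32 without vehicle library 2). Of 113 named genes that passed, none reversed; 67 and 68 did not pass without NAM library 1 and 2, 12 with total counts and 11 without a filter. Of 14 that had not passed, STAR was above 0 with total counts (0.152), upper quartile (0.010) and without vehicle library 1 or NAM library 2 (-0.267 to 0.181 over the 4 left out), HSD17B3 with total counts (0.142), upper quartile (0.025), length correction (0.115) and without vehicle library 2 or NAM library 2 (-0.288 to 0.287), and CYB5A without vehicle library 1 (-0.680 to 0.075). In the simulation, with a dispersion shared by both groups and few genes changed, 1.92% of 1.5-fold changes were called with no length trend. Depth was not varied alone.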

Other observations

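The genes and groups in the next 2 paragraphs, the single genes named for the vehicle libraries, the test of transcript length on these libraries, the length correction of the ribosomal and respiratory lists, the test of scaling on the stress response list and the comparison of aminoacyl-tRNA synthetases were chosen after the values were seen; the other tests were written before their results.

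Several amino acid transporters were higher in NAM-treated cells. Of 16 looked at, 8 rose, 1 fell and 7 did not pass, including the large neutral amino acid transporter SLC7A5 (32.3 ± 0.5 to 134.1 ± 1.4 CPM, log2 fold change 2.05, SE 0.12), the glutamine transporter SLC1A5 (52.1 ± 2.2 to 217.5 ± 1.2 CPM) and SLC43A1 (2.59, SE 0.23), while SLC7A8 fell (-1.23). CYP1A1, a detoxifying enzyme induced through the aryl hydrocarbon receptor, rose from 14.3 ± 0.1 to 79.7 ± 1.2 CPM (2.47, SE 0.13), and CYP1B1 rose 3.59-fold; with AHRR, 3 of 6 targets of that receptor rose and none fell, while NQO1 did not pass (-0.21). SOAT2, which esterifies cholesterol, rose from 34.0 ± 9.6 to 212.1 ± 0.9 CPM (2.64, SE 0.23).

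Of 13 glutathione S-transferases 7 fell, 5 did not pass and GSTM3 rose (0.98). GSTA1 fell from 441.7 ± 186.9 to 43.5 ± 4.0 CPM (-3.34, SE 0.34) and GSTO1 from 49.6 ± 21.2 to 6.94 ± 1.28 CPM; 26.2% of the 50-base windows of GSTA1 occur in another gene. Of 27 actin, tubulin and actin-binding genes 9 fell and none rose, among them ACTG1 (1365 ± 339 to 197.8 ± 8.1 CPM), TUBA1A (888.7 ± 326.7 to 132.6 ± 7.1 CPM) and TUBB (1618 ± 347 to 404.5 ± 12.9 CPM). Without NAM library 1 or 2, 3 of these fell, and without vehicle library 1 and 2, 19 and 20 fell and 1 rose; of the glutathione S-transferases 3 fell without either NAM library and 10 without either vehicle library. Of the amino acid transporters 7 rose without either NAM library, and 11 and 12 rose and 3 and 2 fell without vehicle library 1 and 2, and of the receptor targets 1 and 2 rose without NAM library 1 and 2. The medians of these 4 groups kept their sign under all 3 other scalings, and as the groups were chosen for what was seen in them no test of a group is given. Of the 50-base windows of TUBA1A and TUBA1B, 22.1% and 25.6% occur in another gene. ACTB, which nearly every cell expresses strongly, had estimated counts of 0, 9.54, 66.0 and 67.3 in vehicle 1, vehicle 2, NAM 1 and NAM 2, and TUBA1B 3.07, 4.05, 0 and 0; 4.84% of the windows of ACTB are shared, and why its counts were near 0 was not tested. Such estimates leave other low values in doubt, among them GOLGA4 with 15 and 22 counts in vehicle and 632 and 657 in NAM libraries.

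With each pair's median difference taken out, the median absolute log2 difference was compared over 14776 genes of known length. On this measure the vehicle libraries differed 3.56 times as much as the NAM libraries. Their difference followed transcript length (Spearman rho = -0.355 across 14776 genes, which are not independent), consistent with a recovery of RNA or fragments that differed by length between these libraries. Length, as that of the longest annotated transcript, was not the whole of it, since after each pair's trend was removed the ratio was still 2.98. Single genes differed far more: NES had estimated counts of 18742 in vehicle library 1, 189 in vehicle library 2, 1369 in NAM library 1 and 1478 in NAM library 2, CILP 4068, 21, 90 and 105, and the immediate early gene FOSB 3467, 45.7, 95.7 and 100.1. The design gives no group that parts the vehicle libraries, so no biological explanation was tested.

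The stress response list kept a median log2 change of 0.87 without vehicle library 1 and 0.775 after length correction. This argues against that library and its length trend as the cause. Without vehicle library 1 the spread rests on the NAM pair alone, so no p-value is given for that fit. With all 4 libraries the camera adjusted p was at most 2.88e-11 with a preset correlation, and 0.506 with an estimated one. Scaling moves all genes alike, whereas the list median lay 0.69 above the median of all genes. Camera had already compared the list with other genes, so this gap is no separate test. The list median was 0.683 with DESeq2 size factors, 0.919 with total-count scaling and 0.763 with upper-quartile scaling. A candidate explanation is an amino acid response of the ATF4 type, for which 12 aminoacyl-tRNA synthetase genes described as ATF4 targets, with WARS1, MARS1 and YARS1 at 2.08, 1.64 and 1.40, were compared with 7 other cytosolic ones, whose median was -0.07 (0.14 with total-count scaling). Of the 12, 7 rose and 5 did not pass, EPRS1 being at -0.78 (1 and 2 rose without NAM library 1 and 2, and 10 and 9 rose and 1 fell without vehicle library 1 and 2), and the adjusted p = 0.261 with an estimated correlation. The medians differed by 1.17, but these genes were picked after high values among them had been seen, so the difference lends no support, and this explanation and any effect of the high concentration on the medium stay open.

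The fall of the ribosomal protein and respiratory chain lists may come from vehicle library 1: without it the adjusted p was 0.194 and 0.206. The medians went from -0.45 (SD of the members 0.25) to 0.07 for ribosomal proteins and from -0.52 (SD 0.31) to -0.14 for the respiratory chain. Length correction did not remove the fall of the respiratory chain, whose median was -0.40 after it (camera adjusted p = 0.0237 with the preset correlation, the estimate being 0.72). The correction used the longest annotated transcript, which need not be the one expressed, so it cannot exclude length. For ribosomal proteins the corrected median was -0.33 with adjusted p = 0.196, so the call ended with most of the fall left and length cannot be told apart from other differences of that library.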
